A study of Mus musculus with 4 samples.

How the data were processed

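HT22 cells in 5 µM or 70 µM choline chloride for 48 h gave 4 libraries, 2 of input DNA and 2 of H3K9ac ChIP DNA, which is how they are grouped here, since the labels name the kind of library but not the choline level of each. Per the submitters' processing notes, CASAVA 1.8, Bowtie 1.0.0 and MACS2 (version not given) were used with the mouse build mm10. Per the series' design text, H3K9ac peaks were called against input and the differences between control and supplemented cells were called with the bdgdiff function of MACS2. The file used is the outcome of that last step: per the file headers it holds the regions unique to condition 1 and those unique to condition 2 and no regions common to both. Each region has a position and a score in the authors' deposited table; in MACS2 such a score is a log10 likelihood ratio of the 2 conditions, but the file gives the column no name. How the libraries were scaled to each other before that step is not given in the sources used here, and a deeper or cleaner ChIP library would yield more regions for its condition. The score is the authors' own value per region and was used only to describe, rank or filter regions within the list. The total reads per library are not known here, so no precision could be derived from depth, and intervals cover counting over regions or genes only.

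The design fixed before the data were examined assumed a list of H3K9ac peaks. The list turned out to hold differential regions only, and the planned summaries were kept, so that each describes where H3K9ac was called different between the conditions and not where H3K9ac was present. The tests use all rows, and values for the 2 levels are set side by side without a p-value. No column of values belongs to a single library, and no paired analysis between libraries could be made.

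Positions were set against the GENCODE M21 annotation and the RefSeq GRCm38.p6 sequence, which are of the same build as mm10, on chromosomes 1 to 19, X and Y. All region ends lay inside the chromosomes. Coordinates in the text count from 1. A region was at a start site when it overlapped by at least 1 bp the 1000 bp either side of any annotated transcript start of a protein-coding gene, and such a gene was marked. Shares have exact (Clopper-Pearson) 95% binomial intervals. For comparison, the same region lengths were placed 100 times at random within the same chromosome. By midpoint, regions were put in start-site window, exon, intron or intergenic sequence, in that order of priority. Widths at start sites and elsewhere were compared by a two-sided permutation test of the difference of medians with 100000 resamples.

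A set of 21 gene lists was written before the data were examined: glucocorticoid signalling, choline and phosphatidylcholine metabolism, the methionine and folate cycle, histone acetyltransferases and deacetylases, histone and DNA methylation enzymes, mood-related receptors and transporters, markers of mature neurons, forebrain transcription factors, Hox genes, markers of astrocytes, oligodendrocytes, microglia and leukocytes, fibroblasts and other lineages, housekeeping, cell cycle, immediate early, ribosomal protein, oxidative phosphorylation and lipid synthesis genes, and olfactory and vomeronasal receptors. All listed names were found in the annotation. The share of marked genes in each list was compared with that of all other protein-coding genes (21938 in all) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 21 lists and a threshold of 0.05. Score at a list was described by the median over its marked genes of the strongest start-site region, as a percentile among 10000 random sets of marked genes of the same size. In 100 simulations on the 21938 genes, planted odds of 5 were called every time for the ribosomal protein and cell cycle lists, planted odds of 0.2 in 93 simulations for the other-lineage list and 83 for the neuronal list, and 0.82% of unchanged lists were called. All genes outside the planted lists were marked independently at the same rate. The simulations thus do not cover start-site windows that differ in length or CpG density, nor odds closer to 1.

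Genes were named by a rule written before the data were examined: Nr3c1 with all its regions; in each list up to 4 marked genes with the highest-scoring start-site regions and up to 2 unmarked genes in alphabetical order; the 10 protein-coding genes with the strongest and the 5 with the widest start-site regions; and the 3 strongest regions over 10 kb from any annotated start. Some genes that this rule takes are not reported here. Other settings tried were windows of 500 and 2500 bp, the regions at or above the median score, the midpoint in place of any overlap, all annotated genes, autosomes only, the 5′-most start only and the majority of a region's bases. Added after the data were seen were the 70 µM or 5 µM regions alone, the list without the 2 commonest exact scores, a stratified permutation test of each list against 10000 sets of genes matched on the bases in their start-site windows and the CpG density there (5 classes of each), and the list test without chromosomes 3, 5, 11 and 15.

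Uniqueness of a region was measured as the share of its 32-base words, on either strand, that occur at another place on these chromosomes, and repeats are the lower-case bases of the reference. How reads with several matches were treated is not given in the sources used here. Motifs were searched on both strands within 200 bp of each midpoint and in a stretch of the same length 5 kb away, with the patterns TGASTCA for AP-1, TGACGTCA for CREB, CCGGAAGT for ETS, GGGGCGGGG for SP1, CACGTG for the E-box, CCAATSR for NFY and GNACANNNTGTNC for the glucocorticoid receptor (S is C or G, R is A or G). Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 was used.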

Results

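H3K9ac, the acetylation of lysine 9 on histone H3 that marks active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in HT22 cells, an immortalised mouse hippocampal neuronal line. The cells had been kept for 48 h in 5 µM choline chloride (control) or 70 µM choline chloride (supplemented). Choline is a nutrient used for phosphatidylcholine, acetylcholine and, through betaine, methyl groups. The series holds 4 libraries, 2 of input DNA and 2 of H3K9ac ChIP DNA, so at most 1 ChIP library stood for each choline level. The labels do not say which library had which level. The measurement analysed here is 1 list of 45855 regions in mm10 that the authors' comparison assigned to 1 of 2 conditions. Condition 1 is read as 5 µM and condition 2 as 70 µM, from the order of the levels in the name of the comparison, and every statement on the direction of a difference rests on that reading. Regions that the conditions shared are not in the list, and the read depth of the libraries is unknown. There were no replicates of a choline level, so no difference between the levels could be set against a spread between cultures, and no p-value is given for one.

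The first question was how H3K9ac differed between the 2 choline levels. Nearly all differential regions were assigned to supplemented choline: 45495 regions (99.2% of the list) were called at 70 µM and 360 at 5 µM, 126 regions at 70 µM for each region at 5 µM. The 70 µM regions covered 8.48 Mb and the 5 µM regions 0.0565 Mb. The median width was 170 bp at 70 µM and 149 bp at 5 µM, and no region was narrower than 120 bp. In the authors' deposited table the median score was 6.63 for the 70 µM regions and 10.8 for the 5 µM regions, with a range over the list from 3.08 to 44.48. Of 21938 protein-coding genes, 8602 had a 70 µM region within 1 kb of an annotated transcript start (39.2%), 193 had a 5 µM region there (0.880%), and 130 had both. Of the genes with a 5 µM region, 67.4% thus also had a 70 µM region; no comparison with genes of matched start-site windows was made. Counted over both levels, 8665 protein-coding genes (39.5%) carried a differential region at a start site; they are called marked genes here. An unmarked gene may carry H3K9ac at both levels alike, since shared regions are not listed.

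The series title names Nr3c1, which encodes the glucocorticoid receptor, the nuclear receptor for corticosterone and cortisol. Nr3c1 (ENSMUSG00000024431.15; chromosome 18, 39410545 to 39519421, minus strand) carried 3 regions, all called at 70 µM, and no 5 µM region. The region closest to an annotated start, at 39488883 to 39489077, had a score of 5.01 in the authors' deposited table and overlapped the first exon of transcript Nr3c1-206, which is 5′ untranslated sequence. This region was 66.7% G and C, held 16 CpG sites and had at its centre, at 39488960 to 39488999, the plus-strand sequence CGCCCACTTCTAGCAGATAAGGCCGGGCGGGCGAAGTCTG. The next region, at 39486346 to 39486661, had a score of 9.10 in the authors' deposited table and lay inside the coding part of exon 2 of transcript Nr3c1-201; for 2 other annotated transcripts this exon is the first, and the region lay within 1 kb of their starts. At its centre, 39486484 to 39486523, the plus strand reads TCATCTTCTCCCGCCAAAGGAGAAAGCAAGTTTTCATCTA. The last region, at 39470033 to 39470153, had a score of 8.13 in the authors' deposited table and lay in the intron between exons 2 and 3 of Nr3c1-201, 17139 bp from the nearest annotated start. None of the 32-base words in these 3 regions occurred elsewhere in the genome.

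**Figure D1:**
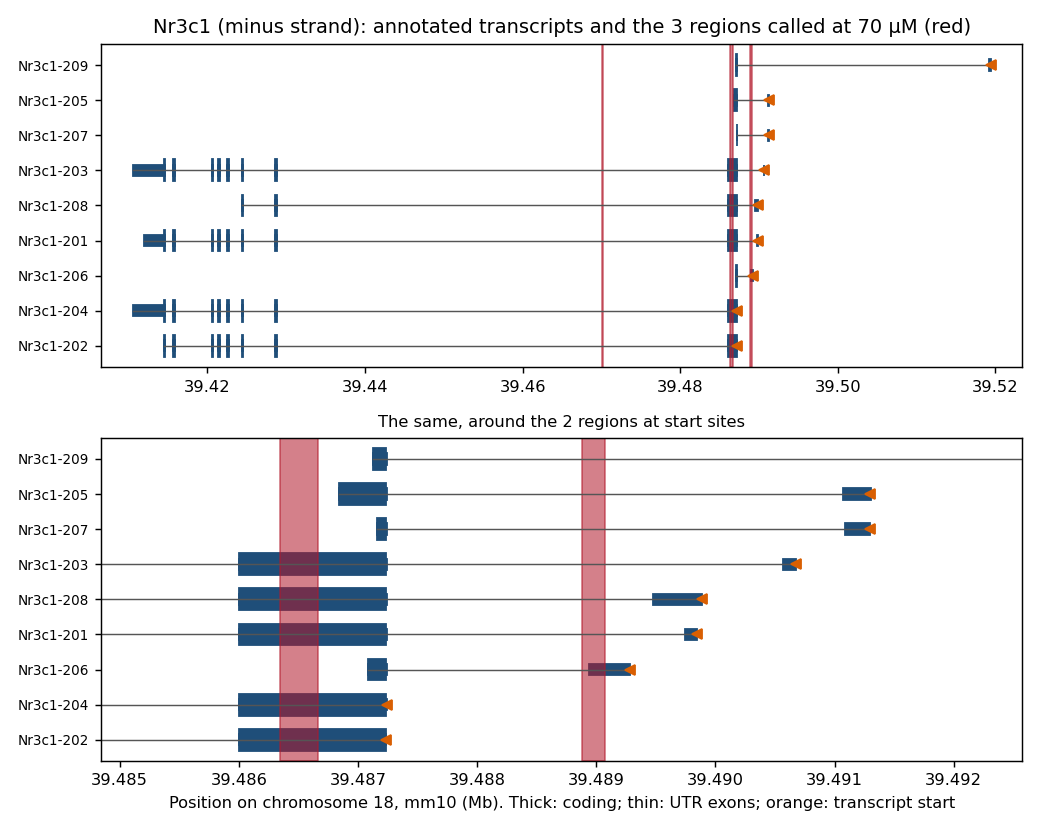
Annotated transcripts of Nr3c1 on the minus strand of chromosome 18 (horizontal axis, position in Mb, mm10), with coding sequence thick, untranslated exons thin and each transcript start in orange. Red bands are the 3 regions called at 70 µM; the lower panel enlarges the 2 that lie within 1 kb of a transcript start.

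As a group, the genes around the receptor did not pass the threshold. Among 26 genes of glucocorticoid signalling, 15 were marked (57.7%, exact 95% interval 36.9 to 76.7), against 39.5% of all other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.0923). Strong start-site regions in the authors' deposited table were at Fkbp5, a co-chaperone of the receptor that glucocorticoids induce (score 22.41), Hsp90aa1, the chaperone that holds the unliganded receptor (21.07), and Ncor1, which encodes a nuclear corepressor (17.80). These were 70 µM regions, at Fkbp5 at 28507272 to 28507451 on chromosome 17. Crh and Avp, which encode the hypothalamic peptides that drive the stress axis, were unmarked. The odds ratio was 2.09. Restricted to 500 bp either side of the starts it was 2.84 and passed the threshold (Fisher's exact test, adjusted p = 0.0180), with windows of 2500 bp it was 1.57 (adjusted p = 0.360), and against genes of matched start-site windows 1.08 (stratified permutation test, adjusted p = 1.0).

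Genes of choline use itself did not stand apart. Of 30 genes for choline and phosphatidylcholine metabolism, 15 were marked (50%, exact 95% interval 31.3 to 68.7, adjusted p = 0.308). The highest scores in the authors' deposited table were at the phospholipases Pld2 (22.93, chromosome 11, 70554688 to 70554883) and Pld1 (9.69), at Aldh7a1, which oxidises betaine aldehyde to betaine (7.20), and at the sphingomyelinase gene Smpd1 (6.50), all at 70 µM. The esterases Ache and Bche were unmarked. In the methionine and folate cycle, into which betaine passes its methyl group, 18 of 30 genes were marked (60.0%, exact 95% interval 40.6 to 77.3), more than among other genes, with an odds ratio of 2.30 and an adjusted p of 0.0437. Its strongest regions in the authors' deposited table were at Mthfd2, a mitochondrial folate enzyme (25.75, chromosome 6, 83311372 to 83311566), the serine hydroxymethyltransferase gene Shmt1 (22.15), Ahcyl1 (19.10) and Ftcd (17.97), whereas Bhmt, the betaine-homocysteine methyltransferase gene, and Aldh1l2 were unmarked. The call on this list ended under 6 of the 9 other settings. In 3 of them the odds ratio was 1.59 or lower: windows of 500 bp (1.39), the 5′-most starts alone (1.59) and matched start-site windows (1.46, stratified permutation test, adjusted p = 0.451). It stayed between 2.193 and 2.502 under the other 3, which were autosomes only, no chromosomes 3, 5, 11 and 15, and only the regions at or above the median score.

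Genes of chromatin enzymes were marked more often than other genes. Of 26 histone acetyltransferase and deacetylase genes, 19 were marked (73.1%, exact 95% interval 52.2 to 88.4, odds ratio 4.16, adjusted p = 0.00196), and of 32 histone and DNA methylation enzyme genes, 22 (68.8%, exact 95% interval 49.99 to 83.9, odds ratio 3.38, adjusted p = 0.00196). The acetylation list was led in the authors' deposited table by the deacetylase genes Sirt3 (19.01), Hdac11 (18.89) and Sirt7 (17.52) and by the acetyltransferase gene Kat5 (17.02), while Hat1 and Hdac2 were unmarked. The score of 19.01 is the commonest exact score in the authors' deposited table, shared by 2552 regions, so the order of the genes that carry it, here and below, is of limited meaning. The methylation list was led there by Tet3, a 5-methylcytosine dioxygenase gene whose strongest region was a 5 µM region (22.9, chromosome 6, 83440728 to 83440856) beside 3 70 µM regions. The demethylase gene Kdm5c (22.60) and the DNA methyltransferase genes Dnmt1 (20.43) and Dnmt3a (19.69) followed in the authors' deposited table with 70 µM regions, and Dnmt3l and Ezh1 were unmarked. Against genes matched on the length and CpG density of their start-site windows, neither list stood apart (stratified permutation test, adjusted p = 0.457 for acetylation and 0.618 for methylation). The acetylation list also lost its call with the 5′-most starts alone (odds ratio 2.07, Fisher's exact test, adjusted p = 0.0932). Without chromosomes 3, 5, 11 and 15, which left 12 of 19 genes marked, the call was lost too (odds ratio 2.95, Fisher's exact test, adjusted p = 0.0553). With only the regions at or above the median score, both lists kept their call. The odds ratios there were 6.82 for acetylation and 3.51 for methylation (Fisher's exact test, adjusted p = 3.6e-05 and 0.00862).

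The 6 lists with the largest shares of marked genes ran from ribosomal proteins to housekeeping genes, with histone acetyltransferases and deacetylases next. Ribosomal protein genes were marked in 57 of 67 cases (85.1%, exact 95% interval 74.3 to 92.6, odds ratio 8.78, adjusted p = 2.02e-13), with the highest scores in the authors' deposited table at Rpl24 (18.55), Rps7 (18.27), Rpl5 (12.60) and Rpl23 (11.15). Rpl19 and Rpl29 were unmarked. Cholesterol and fatty acid synthesis had 22 of 27 genes marked (81.5%, odds ratio 6.75, adjusted p = 5.91e-05), with scores in the authors' deposited table at Srebf1, the sterol response regulator (17.27), the farnesyl diphosphate synthase gene Fdps (10.57) and the fatty acid synthase gene Fasn (6.70). Hmgcs1 and Idi1 of the same pathway were unmarked. Of 34 cell cycle and replication genes, 27 were marked (79.4%, odds ratio 5.92, adjusted p = 2.28e-05), among them Mcm2 (19.01), Cdk6 (9.86), Ccnd1 (9.79) and Rb1 (9.37) by the scores of the authors' deposited table, but not Bub1 or Cdk1. Oxidative phosphorylation had 27 of 36 genes marked (75.0%, odds ratio 4.61, adjusted p = 8.49e-05), led in the authors' deposited table by the complex I subunit genes Ndufa10 (19.01), Ndufs4 (13.84), Ndufs3 (13.18) and Ndufb8 (9.05), with Atp5a1 and Atp5b unmarked. Housekeeping genes were marked in 22 of 30 cases (73.3%, odds ratio 4.22, adjusted p = 0.000823), among them Gpi1 (21.12), Tfrc (20.63) and Eef1a1 (12.25) by the scores of the authors' deposited table, and with Chmp2a and Gusb unmarked. Immediate early genes, which neurons and other cells switch on within minutes of stimulation, were marked in 20 of 27 cases (74.1%, exact 95% interval 53.7 to 88.9, odds ratio 4.38, adjusted p = 0.00149). They were led in the authors' deposited table by Nr4a1 (11.12), Maff (8.26), Zfp36 (6.23) and Jun (6.07), while Arc and Atf3 were unmarked. Against genes of matched start-site windows, the ribosomal protein list (odds ratio 4.17, stratified permutation test, adjusted p = 0.0021), oxidative phosphorylation (2.64, 0.0286) and lipid synthesis (3.04, 0.0366) passed with smaller odds ratios, and the cell cycle (2.54, 0.0562), immediate early (2.37, 0.0836) and housekeeping lists (1.91, 0.197) no longer did, the first 2 with odds ratios about as large as that of oxidative phosphorylation. With only the regions at or above the median score, none of these 6 lists passed, and the odds ratio of the immediate early genes turned to 0.466.

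Genes of differentiated neurons and of other tissues were marked less often. Of 32 genes of mature neurons and synapses, 6 were marked (18.8%, exact 95% interval 7.21 to 36.4, odds ratio 0.353, adjusted p = 0.0338). These included Nlgn1 and Rbfox3 (19.01 each), Syn1 (6.88) and the neuronal enolase gene Eno2 (6.27), whose strongest region was a 5 µM region, by the scores of the authors' deposited table, and the calcium/calmodulin kinase genes Camk2a and Camk2b were unmarked. Nlgn1 and Rbfox3 carry the commonest exact score, and without the regions at the 2 commonest scores 4 genes of the list were marked (odds ratio 0.225, Fisher's exact test, adjusted p = 0.00316). Of 38 genes of other lineages, 5 were marked (13.2%, odds ratio 0.232, adjusted p = 0.00176): in the authors' deposited table Myl2 of muscle (22.87), Sftpb of lung (19.01), the keratin gene Krt5 (9.76) and the elastase gene Cela1 (5.39) came first, and Actn2 and Afp were unmarked. Only 13 of 1466 olfactory and vomeronasal receptor genes were marked (0.887%, exact 95% interval 0.470 to 1.51, odds ratio 0.0122, adjusted p = 1.98e-304). Against genes of matched start-site windows its odds ratio was 0.222 (stratified permutation test, adjusted p = 0.0021), much closer to 1. The neuronal list lost its call with windows of 2500 bp (Fisher's exact test, adjusted p = 0.281), and the other-lineage list against matched start-site windows (adjusted p = 0.145). Both lost it with only the regions at or above the median score.

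For the remaining lists the share of marked genes did not pass the threshold. Of 28 mood-related receptor and transporter genes, 6 were marked (21.4%, adjusted p = 0.0757), with scores in the authors' deposited table of 16.25 at Gal, which encodes galanin, 6.83 at the tyrosine hydroxylase gene Th and 5.41 at Creb1, and with the receptor genes Cnr1 and Drd1 unmarked. Of 28 forebrain transcription factor genes, 7 were marked (25%, adjusted p = 0.156), among them Zbtb20 (19.002), Nr2f2 (6.08) and Nr2f1 (5.89) by the scores of the authors' deposited table, with Bcl11b unmarked; against matched start-site windows this share was lower than in other genes (adjusted p = 0.00735). Of 39 Hox genes, 13 were marked (33.3%, adjusted p = 0.539), with the highest scores in the authors' deposited table at Hoxc12 (21.26), Hoxc5 (17.41), Hoxc4 (12.54) and Hoxa10 (8.90), and Hoxa11 unmarked. Markers of other cell types were 3 of 12 marked for astrocytes (Fisher's exact test, adjusted p = 0.426), 4 of 13 for oligodendrocytes (0.584), 3 of 18 for microglia and leukocytes (0.0757) and 15 of 24 for fibroblasts and mesenchyme (0.0553). The strongest of each in the authors' deposited table were Glul (19.01), Sox10 (15.99), Lck (23.26) and Thy1 (17.59). Slc1a3 (6.16) and Gja1 (5.61) were the other marked astrocyte genes in the authors' deposited table, Cnp (7.84) and Cspg4 (6.32) followed in oligodendrocytes and Col1a2 (8.24) and Twist2 (7.71) in fibroblasts, and Aif1, a microglial gene, had a score of 13.96. Aqp4, Mag, Cd3d and Acta2 were among the unmarked. The microglia and leukocyte list passed the threshold, below other genes, with windows of 2500 bp (Fisher's exact test, adjusted p = 0.0274). The fibroblast list passed the threshold with windows of 500 bp (Fisher's exact test, odds ratio 2.46, adjusted p = 0.0468), with only the 70 µM regions (2.59, 0.0387), without the 2 commonest scores (2.63, 0.0367) and against matched start-site windows (2.66, stratified permutation test, 0.0357).

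**Figure D2:**
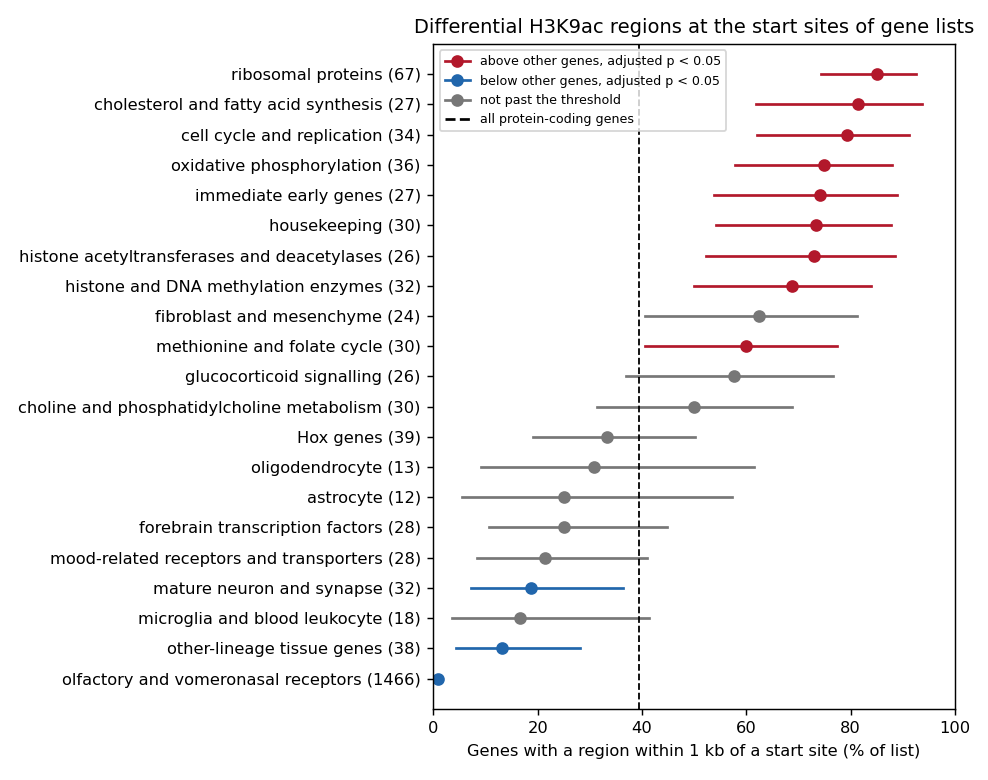
Share of each gene list with a differential region within 1 kb of a start site (horizontal axis, percent of the list; the number of genes is in parentheses), with exact 95% intervals; the dashed line is the 39.5% of all protein-coding genes. Ribosomal proteins are highest with 85.1% and olfactory and vomeronasal receptors lowest with 0.887%.

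In all, 9 of the 21 lists were marked more often than other genes, 3 less often, and 9 did not pass the threshold. Against genes of matched start-site windows, 4 lists were marked more often, of which 3 had been so without matching, and 3 less often, of which 2 had been so. With only the regions at or above the median score, 2 lists were marked more often, those of acetylation and methylation enzymes, and 1 less often, the olfactory and vomeronasal receptors. Genes are not replicates of a choline level, so these tests describe the list of regions and not the effect of choline. By score, 3 lists stood above random sets of marked genes of the same size, and none below. The score of a gene is that of its strongest start-site region, so genes with more regions can stand higher. The random sets were not matched on the number of regions or on start-site windows. The median score in the authors' deposited table was 11.8 at the histone acetyltransferase and deacetylase genes (percentile 99.9) and 13.1 at the 13 marked olfactory and vomeronasal receptor genes (99.9), against 5.68 over all marked genes. The 3 marked microglia and leukocyte genes stood at percentile 99.7. The 2 most often marked lists had medians of 5.31 (ribosomal proteins) and 5.17 (lipid synthesis) in the authors' deposited table, inside the range of random sets.

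The next question was where in the genome the regions lay. A share of 28.9% of the 70 µM regions (13147 of 45495, exact 95% interval 28.5 to 29.3) and 46.9% of the 5 µM regions (169 of 360, 41.7 to 52.2) overlapped the window of 1 kb either side of a protein-coding start. Random placement of the same lengths gave 4.11 to 4.49% and 1.94 to 6.67% over 100 placements. Over both levels, the share was 29.0%, 6.71 times the mean of the placements. By midpoint, 27.7% of all regions lay in a start-site window, which makes up 3.60% of the genome, 7.19% in an exon (3.69% of the genome), 40.1% in an intron (38.1%) and 25.03% between genes (54.6%). At 5 µM these shares were 45.3%, 4.17%, 31.7% and 18.9%. Within 1 kb of the nearest 5′-most start, 5545 of the 70 µM regions lay downstream, inside the transcribed side, and 2612 upstream, so 68.0% were downstream (exact 95% interval 67.0 to 69.0). At 5 µM there were 61 downstream and 55 upstream (52.6%, 43.1 to 61.9). Other annotated starts of a gene lie downstream of its 5′-most start by definition, so regions at them can add to the downstream counts. Regions more than 10 kb from any annotated start made up 29.8% of the 70 µM regions and 20% of the 5 µM regions.

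**Figure D3:**
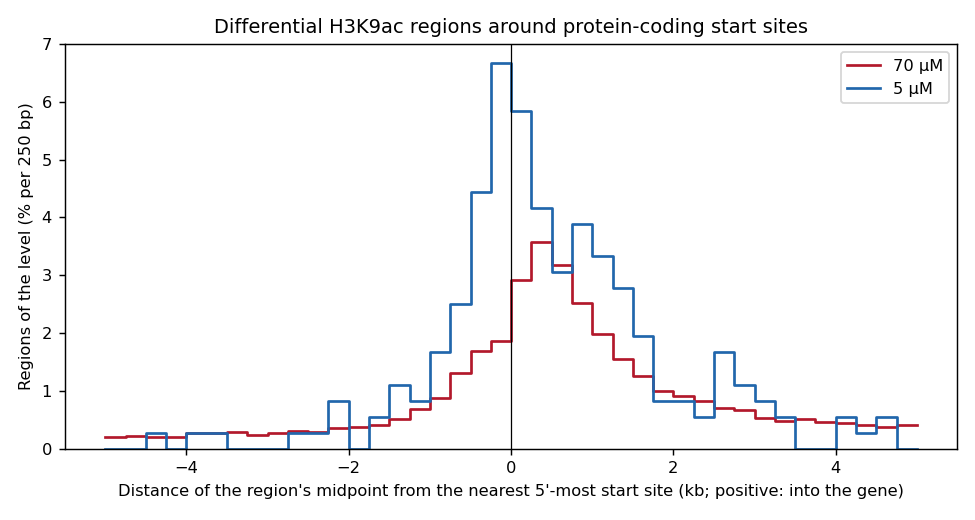
Regions per 250 bp (vertical axis, percent of the regions of a level) by the distance of their midpoint from the nearest 5′-most protein-coding start (horizontal axis, kb, positive into the gene), for 70 µM (red) and 5 µM (blue). The 70 µM regions reach 3.57% between 250 and 500 bp downstream, and the 5 µM regions 6.67% in the 250 bp before the start. The latter rests on 24 regions, against 21 in the 250 bp after the start.

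Regions at start sites were wider, with a median of 184.5 bp (n = 13316) against 165 bp elsewhere (n = 32539), a difference of 19.5 bp (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give; regions of 1 list are not replicates). The 5 genes with the widest start-site regions, all at 70 µM, were Rpl38, a ribosomal protein gene (1118 bp, chromosome 11, 114669296 to 114670413), the oncogene Myc (1101 bp, chromosome 15, 61985573 to 61986673), Lrp1, a lipoprotein receptor gene (986 bp), Gm14326 (942 bp) and Bcar3 (935 bp). At Gm14326, 86.1% of the 32-base words of the region occur elsewhere in the genome.

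Scores ran the other way. In the authors' deposited table the median score of the 70 µM regions was 4.99 at start sites and 8.70 elsewhere, and of the 5 µM regions 8.30 and 12.5. The share of 70 µM regions at start sites was 48.4% for scores over 3 and up to 4 (exact 95% interval 47.1 to 49.8), 21.1% for scores over 8 and up to 10, and 8.25% for scores over 18 and up to 20 (7.47 to 9.08). For the 5 µM regions, with 5 to 67 regions per bin, the share went up and down between 31.6% and 66.7% without a steady fall; whether the levels differ in this was not tested.

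**Figure D4:**
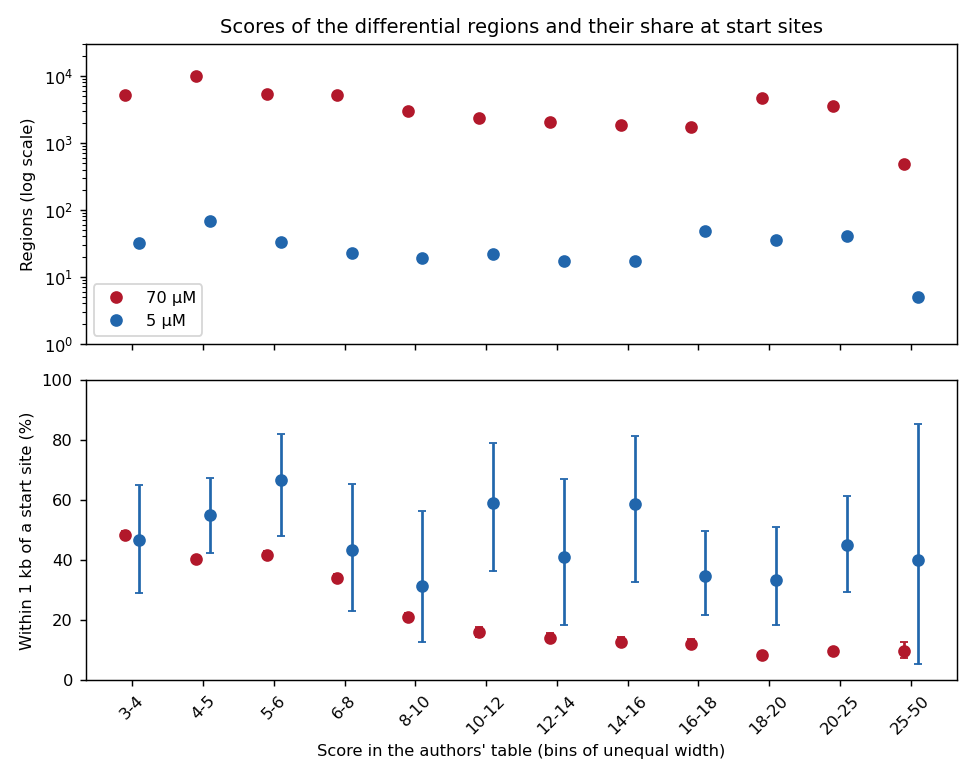
Number of regions (upper panel, log scale) and share of regions within 1 kb of a start site (lower panel, percent, with exact 95% intervals) by score in the authors' deposited table, in bins of unequal width, for 70 µM (red) and 5 µM (blue). At 70 µM the share falls from 48.4% in the lowest bin to 8.25% for scores over 18 and up to 20.

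The protein-coding genes with the strongest start-site regions were a mixed set. Any annotated transcript start counts here, and some of these regions lay at internal starts. At Bcl9, Pfas, Mrpl58 and Cdc26 the region lay inside the gene, more than 1 kb from its 5′-most start. The 5′-most starts of Bcl9 and Pfas, both on the minus strand, are at 97297917 and 69008460. In the authors' deposited table the highest score, 44.48, was at Gm10800 (chromosome 2, 98666510 to 98667369), where 97.2% of the bases are marked as repeats. Bcl9, a cofactor of beta-catenin, followed with 31.91 (chromosome 3, 97213902 to 97214193), then Pfas of purine synthesis with 30.43 (chromosome 11, 68993803 to 68994004) and the urinary protein gene Mup5 with 29.73, all at 70 µM in the authors' deposited table. Of the 32-base words of the Mup5 region, 78.5% occur elsewhere. A 5 µM region with a score of 29.50 in the authors' deposited table, the highest of that level, lay within 1 kb of annotated starts of both Gnb1l and Rtl10 (chromosome 16, 18498879 to 18499069, in untranslated exon sequence). The remaining genes by score in the authors' deposited table, each with a 70 µM region, were the zinc finger genes Zfp984 (29.36, with 49.7% of its words found elsewhere) and Zfp385c (29.23), the mitochondrial ribosomal gene Mrpl58 (29.17) and Cdc26 of the anaphase-promoting complex (28.31). More than 10 kb from any annotated start, the 3 highest scores in the authors' deposited table were 35.15 in an intron of Slit3, an axon guidance gene (chromosome 11, 35299967 to 35300207), 34.42 in an intron of Tbc1d22a (chromosome 15, 86319619 to 86319819) and 34.02 between genes on chromosome 4 (114725478 to 114725677), where 70.0% of the bases are marked as repeats.

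Chromosomes differed in how many of their genes had a 70 µM region at a start site. The share was highest on chromosome 15 (439 of 785 genes, 55.9%, exact 95% interval 52.4 to 59.4), followed by chromosome 11 (49.6%) and chromosome 3 (47.9%), and lowest among autosomes on chromosome 14 (219 of 902 genes, 24.3%, 21.5 to 27.2). On the X chromosome it was 21.4% (18.8 to 24.2). Regions more than 50 kb from any annotated start, called at 70 µM, numbered 10.7 per Mb of such sequence on chromosome 15 and 1.03 on chromosome 14. There were 213 regions at 70 µM for each region at 5 µM on chromosome 15 and 64.3 on chromosome 13. These ratios rest on 18 and 19 regions at 5 µM. The ratio was about as high on chromosomes 17 (212.8, with 12 regions at 5 µM) and 19 (212.5, with 8).

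**Figure D5:**
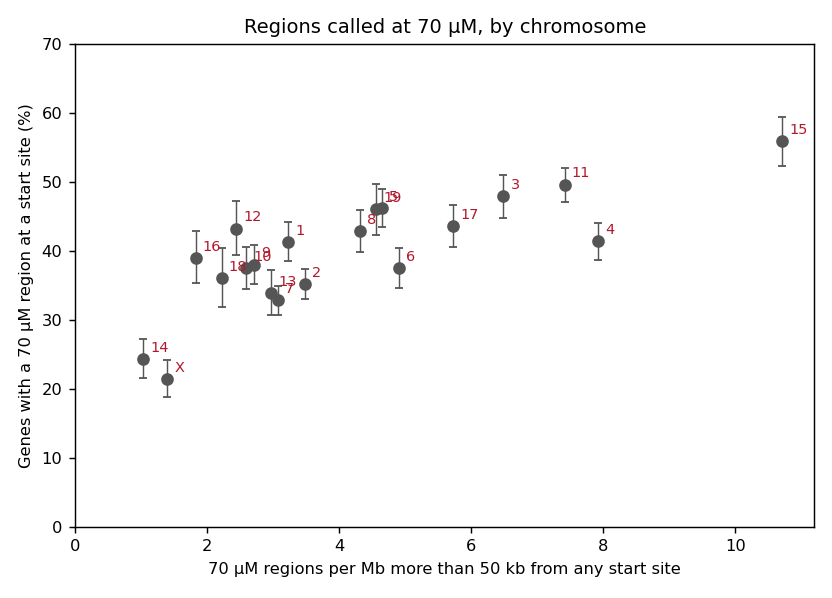
Share of protein-coding genes with a 70 µM region at a start site (vertical axis, percent, exact 95% intervals) against 70 µM regions per Mb more than 50 kb from any annotated start (horizontal axis), 1 point per chromosome, without Y. Chromosome 15 stands highest with 55.9% and 10.7 per Mb, and chromosome 14 and the X chromosome lowest.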

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

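Most values that changed followed the score or the window. The share of regions at start sites was 20.5% with windows of 500 bp, 40.4% with 2500 bp, 27.7% by midpoint and 32.5% with all annotated genes, as the size and number of windows imply. It was 15.4% among regions at or above the median score and 30.8% without the 2 commonest scores, where only 7.37% of the regions at the commonest one lay at start sites; explanations for the place of high scores are weighed in the closing part. Among the regions at or above the median score, 3213 genes were marked, 3 lists passed the threshold (2 above and 1 below other genes), and the classes by midpoint were 14.5% start site, 7.96% exon, 47.2% intron and 30.4% intergenic. The odds ratio of immediate early genes fell below 1 there, to 0.466 (Fisher's exact test, adjusted p = 0.629), and 99.0% of those regions were 70 µM regions. With only the 5 µM regions, 193 genes were marked. Against matched start-site windows, 7 lists passed: the ribosomal protein, oxidative phosphorylation, lipid synthesis and fibroblast lists above other genes, and the neuronal, forebrain transcription factor and olfactory and vomeronasal receptor lists below them. The fibroblast and forebrain lists had not passed without matching. The number of lists passing was 10 to 13 under the other settings, against 12. Of the 12 lists with a call, only the olfactory and vomeronasal receptors kept it under all 9 settings. Of the 9 without one, 5 stayed without a call throughout. Regions at start sites were wider by 18 to 25 bp under each setting tried, and 4 lists stood out by score with windows of 2500 bp, against 3. The settings without the commonest scores, by level, against matched windows and without the 4 chromosomes were chosen after the data were seen. The planned change to another strength column was not run, because the list has 1 score. No paired analysis was possible because the list holds no value for a single library. Depth is unknown, so how many 5 µM regions were missed could not be estimated.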

Other observations

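The tests in this part were chosen after the regions had been seen, except the odds ratio of the ribosomal protein list, which was planned as a list test and chosen as a test of depth or yield only afterwards. Sequence motifs differed between the regions and their flanks. The AP-1 site, bound by Fos and Jun proteins, was found within 200 bp of the midpoint in 17.3% of the 191 5 µM regions outside start-site windows (exact 95% interval 12.2 to 23.4), against 5.76% of stretches 5 kb away (exact McNemar test, p adjusted over 42 motif tests = 0.00494). In the 32348 70 µM regions outside start-site windows it was found in 8.66% against 6.95% of flanks (exact McNemar test, adjusted p = 3.74e-15), and at start sites it was rarer than in the flanks (4.75% against 6.94%, exact McNemar test, adjusted p = 2.22e-13). Whether the levels differ in AP-1 sites was not tested. At start sites of 70 µM regions, 4 of the motifs were more frequent than in flanks: SP1 in 7.53% against 1.57% (exact McNemar test, adjusted p = 1.17e-125), ETS in 2.22% against 0.510% (2.09e-34), CREB in 0.662% against 0.259% (9.43e-06) and the E-box in 7.17% against 5.65% (4.68e-06). The promoter motif NFY was not (11.46% against 11.99%, exact McNemar test, adjusted p = 0.394). The palindromic glucocorticoid receptor site was about as frequent in 70 µM regions outside start sites as in their flanks (0.696% against 0.662%, exact McNemar test, adjusted p = 0.917) and less frequent at start sites (0.517% against 0.821%, adjusted p = 0.0148). The patterns of SP1, ETS, CREB and the E-box each contain CG, and those of AP-1, NFY and the glucocorticoid receptor do not require it. Flanks were not matched on base composition or CpG density, so these differences cannot be told apart from a difference in composition. The McNemar test takes regions as independent, but the searched stretches of neighbouring regions can overlap, so the p-values may be too small. Regions are not replicates of a choline level, so these values describe the list.

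Genes with a 5 µM region at a start site often had 70 µM regions too. In the authors' deposited table Tet3 had 1 region at 5 µM (score 22.85) and 3 at 70 µM, and Eno2, Junb and Col1a2, the other listed genes with a 5 µM region, also had 70 µM regions. Junb lies outside the rule for named genes and was chosen after its values were seen.

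Nearly all regions were called at 70 µM, and a difference in depth or ChIP yield between the 2 ChIP libraries could give the same imbalance. The odds ratio of the ribosomal protein list (8.78, and 4.17 against matched start-site windows) decides nothing here, since a general rise in H3K9ac at 70 µM choline would mark the same genes. Such a rise stays open, untested. With at most 1 ChIP library per level and no depths, the 2 explanations cannot be told apart.

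Chromosomes 15, 11 and 3 carried more marked genes than chromosome 14 or X. Longer or more CpG-rich start-site windows do not account for all of it. On chromosome 15, 440 genes were marked, where sets matched on both features gave 335 to 382. Of the 21 chromosomes, 13 lay outside their range and 8 inside. The windows can account for part of the pattern. Matched sets gave on average 45.7% marked genes on chromosome 15, 34.9% on chromosome 14 and 30.0% on X. The observed shares were 56.1%, 24.5% and 21.6%. A candidate explanation is a different number of copies of these chromosomes in HT22 cells. Over 20 chromosomes the share of marked genes rose with the density of 70 µM regions more than 50 kb from any start (Spearman's rho = 0.723, permutation p = 0.00048; Pearson's r = 0.786, permutation p = 3e-05), and without chromosomes 4 and 15 rho was 0.699 and r 0.780. Both measures count 70 µM regions of the same list, so any factor acting on a whole chromosome could give this correlation. The correlation therefore does not single out copy number. Copy number was not measured, and a chromosome-wide difference in acetylation remains open.

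Regions with high scores lay mostly away from start sites, and 2552 regions, all at 70 µM, shared 1 exact score of 19.01 in the authors' deposited table, 7.37% of them at start sites. Scores built from steps of a few reads are a candidate explanation: of 31317 regions scoring between that value and the second commonest, 4.01, 5.49% were whole-base mixtures of the 2 within 0.005 bases, 5.49 times the 1% expected by chance. Above 19.01, 82 of 5466 regions fell on such steps (1.5%, 1.5 times chance, short of the ratio of 2 set for this test), so for the highest scores this explanation stays open. Such steps were not compared between start sites and elsewhere. These shares thus bear on how scores arise, and cannot decide why high scores lay away from start sites. Exactly repeated sequence does not account for most of the regions at 19.01, since 14.3% of 300 sampled regions at the commonest score were made mostly of 32-base words found elsewhere (exact 95% interval 10.6 to 18.8), against 15.4% of 292 random places. Of 300 sampled regions scoring under 6, 8.67% were so made outside start sites and 2.0% of another 300 at start sites, both less than at the commonest score (differences not tested). Words had to match exactly on these chromosomes, so diverged copies, or copies missing from the reference, stay open. Bases marked as repeats made up 29.5% of the regions at 19.01, 20.1% of all 70 µM regions and 32.5% of random places for the former. Distal elements with AP-1 sites are not favoured: outside start sites the excess of AP-1 over the flanks was 0.340 percentage points at scores of 16 or more and 2.97 at scores under 6, a difference of -2.63 (permutation p = 1e-05, the smallest possible). Other kinds of distal element remain open. Of the 7 motifs, only NFY passed the threshold in those 70 µM regions with scores of 16 or more (14.6% against 13.4% of flanks, exact McNemar test, adjusted p = 0.0481).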
